A study of Homo sapiens with 12 samples.

How the data were processed

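Gene expression was measured with Affymetrix oligonucleotide arrays in 2 human lines of pancreatic cancer cells. BxPC-3 cells and AsPC-1 cells were each left untreated or given the phorbol ester PMA at 1 µM for 4 h after overnight culture in low serum. The 12 arrays form 4 groups of 3. The 3 arrays of a group came from 3 different cell passages, per the labels. The p-values rest on the spread between passages within groups, pooled over the 4 groups of these 2 lines. A p-value or SE for one line therefore also holds the spread of the other. The vehicle given to the untreated cells is not given in the sources used here.

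The authors deposited 1 table of signal intensity on a linear scale, with 54675 probe sets and 12 columns. Per the submitters' processing notes the values were made with MAS5, whose version is not given in the sources used here. The mean signal of each array, with the top and bottom 2% of probe sets trimmed, lay between 99.982 and 99.986 on the 12 arrays, so they share a scale. Detection calls and scanner files were not used here, so a low signal was not tested against background. The number of arrays limits the precision, and array signal carries no read depth.

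Signals were turned into log2(signal + 3), and fold changes are on that scale, which understates the change of dim genes. The pseudocount of 3 is the rounded median over arrays of the 20th percentile of signal. No further normalization was applied. The 62 control probe sets were left out. In the annotation table, 41091 probe sets had 1 gene symbol, 1801 had several and 11721 had none, and probe sets of the last 2 kinds were not named. Of the probe sets with 1 symbol, 41037 matched the reference gene table (GRCh38.p14, used for names only) by Entrez ID, and 0 symbols changed. For each of 19775 genes the probe set with the highest mean was kept. Genes above the array's 40th percentile (signal 8.18 to 10.2) on at least 3 arrays were tested, which gave 16099 genes. Of these, 9699 had over 1 probe set. Probe sets whose names carry the marks s or x can also hit related transcripts.

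Group means were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with an intensity trend, 8 residual degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05. Tests were two-sided. Contrasts were PMA against untreated in each line, BxPC-3 against AsPC-1 after PMA and untreated, and the difference of the PMA responses. For single genes, an exact test of 3 against 3 arrays cannot go below p = 0.1. The 25 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. An estimated correlation and fry, which asks whether a list's genes move on balance one way, were alternatives. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

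Named genes follow a rule. Per comparison it takes the 6 largest rises and 6 largest falls among genes past the threshold whose groups do not overlap (no overlap condition for the difference of responses), up to 2 members past the threshold from each list, and MMP1, MMP9, PLAU, PLAUR and CDH1 whatever their result, with SMAD4 and CDKN2A between lines. 1 further fixed gene is not reported here. The comparisons, lists, rule and most alternatives were fixed before the data were examined. Alternatives were other scalings, pseudocounts, filters and probe set summaries, eBayes without trend, the arrays of the comparison alone, a replicate block, a 2-fold minimum, and leaving out each array in turn.

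Treated and untreated arrays with the same replicate number share a passage within a line, per the labels, so the numbers pair them. Deviations from the group means of paired arrays correlated at 0.411, 0.206 and 0.157 in AsPC-1 and at -0.054, -0.126 and -0.059 in BxPC-3, across genes. Between lines the arrays share only a number.

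The fit was tested on simulated data for PMA in BxPC-3, with 16099 genes, 5 rounds and 200 changed genes a round. It recovered 29.2% of 2-fold and 68% of 4-fold changes, and 6.18% of calls were false. It made 0 calls in the unchanged comparison. The simulated noise was drawn independently for each gene and array, with the same SD of a gene in all 4 groups. It held no outlying array and no deviations shared within a passage, so these rates may not hold for the real arrays.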

Results

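The series asked how PMA, an activator of protein kinase C that its design text describes as an inducer of invasion, changes gene expression in a line from a primary pancreatic tumour (BxPC-3) and in a line from ascites (AsPC-1), which the series calls metastatic. Each of the 4 groups held 3 arrays. The ratio of 3' to 5' signal of the GAPDH control probe sets lay between 0.987 and 1.12 on all 12 arrays. The ACTB ratio was 2.56, 2.95 and 4.15 in the untreated BxPC-3 arrays and 1.84, 1.99 and 2.02 in the BxPC-3 PMA arrays, so it moved with treatment in that line. In AsPC-1 it was 2.21, 2.27 and 2.24 untreated and 2.12, 2.32 and 1.79 after PMA. One array stood apart from its group. AsPC-1 PMA replicate 1 (passage 8) correlated at r = 0.921 with the other AsPC-1 PMA arrays across genes, against 0.964 with the untreated array of its own passage. Its GAPDH ratio was 1.10. Counts are therefore also given without it.

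In BxPC-3, PMA raised the urokinase receptor PLAUR from a signal of 179 ± 50.2 to 5540 ± 164 (SD, n = 3), a log2 change of 4.96 ± 0.46 (SE, adjusted p = 6.9e-05). Its ligand PLAU, the urokinase protease, rose by 2.63 ± 0.39. The interleukin IL36G (5.31 ± 0.38), the cornified envelope gene SPRR2B (5.35 ± 0.37), the epidermal transcription factor GRHL3 (4.58 ± 0.54) and C11orf96 (5.50 ± 0.98) were among the largest rises, SPRR2B on a probe set that related transcripts can share. The guanine nucleotide exchange factor VAV3 had the largest fall among genes whose groups did not overlap, by 3.39 ± 0.40, from 369 ± 60.2 to 33.9 ± 14.7, and ZNF488 fell by 3.22 ± 0.71. The collagenase MMP1 (0.99 ± 0.54, adjusted p = 0.328), MMP9 (0.50 ± 0.38, adjusted p = 0.502) and E-cadherin CDH1 (0.40 ± 0.24, adjusted p = 0.384) did not pass the test. MMP1 passed when AsPC-1 PMA replicate 1 was left out of the shared spread (adjusted p = 0.032). Its BxPC-3 signals were 1234, 2055 and 1266 untreated and 4072, 1966 and 3179 after PMA, so the groups overlapped.

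The ACTB ratio was lower on each BxPC-3 PMA array than on each untreated one, as given above, and the list results for this line stand beside that difference. Of 26 tested immediate-early transcription factors 9 rose and 0 fell, 13 adjusted over the list alone, among them KLF6 (2.60) and EGR3 (2.48), with a camera adjusted p = 1.22e-10 and an adjusted p = 0.211 with an estimated correlation. Of 22 ERK and PKC feedback genes 8 rose (11 adjusted over the list alone), with the phosphatases DUSP5 (3.08) and DUSP10 (2.62), adjusted p = 4.63e-07 and adjusted p = 0.109 with an estimated correlation. Of 20 NF-kB target genes 7 rose (12 adjusted over the list alone), with BCL2A1 (3.56) and TNFAIP3 (2.89), adjusted p = 8.83e-08 and adjusted p = 0.211 with an estimated correlation. Cytokines and chemokines had 5 of 26 rising (9 adjusted over the list alone), with LIF (3.62) and IL1A (2.64), adjusted p = 2.6e-06 and adjusted p = 0.19 with an estimated correlation. Growth factors had 4 of 19 (8 adjusted over the list alone), with GDF15 (3.90) and HBEGF (2.84), adjusted p = 0.000429 and adjusted p = 0.109 with an estimated correlation. Growth arrest and apoptosis genes had 4 of 20 rising and 1 falling (9 and 1 adjusted over the list alone), with CDKN1A (3.06) and PMAIP1 (1.77), adjusted p = 6.52e-05 and adjusted p = 0.0379 with an estimated correlation, a call lost with the passage as a block (adjusted p = 0.182 with an estimated correlation). When AsPC-1 PMA replicate 1 was left out of the shared spread, 20 immediate-early, 14 NF-kB target, 10 cytokine and 8 growth factor genes rose, and 8 growth arrest genes rose and 2 fell. With an estimated correlation, adjusted p was then 0.00169 for immediate-early and NF-kB target genes, 0.00904 for cytokines, 0.0135 for growth factors and growth arrest genes and 0.0296 for ERK and PKC feedback genes. In the fit with the passage as a block, 9 cytokine and 7 growth arrest genes rose.

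Epithelial junction genes also shifted up in BxPC-3, with 9 of 26 rising and 2 falling (10 and 3 adjusted over the list alone), adjusted p = 4.06e-06 and adjusted p = 0.132 with an estimated correlation. The tight junction gene CLDN4 rose from 86.4 ± 15.9 to 1780 ± 216 and OVOL1 by 3.51 ± 0.47. Among 21 plasminogen system genes 4 rose (6 rose and 1 fell adjusted over the list alone), adjusted p = 0.0188 and adjusted p = 0.151 with an estimated correlation. Among 24 integrin, laminin and hyaluronan genes 4 rose and 1 fell (5 and 1 adjusted over the list alone), with LAMB3 (1.45) and HAS2 (0.98), adjusted p = 0.0277 and adjusted p = 0.19 with an estimated correlation. Of 29 metalloproteinases 1 rose, MMP7 (1.08 ± 0.19), with 1 adjusted over the list alone, adjusted p = 0.025 and adjusted p = 0.136 with an estimated correlation. Of 20 hypoxia and glycolysis genes limma called 0 over all genes tested, 8 rising at an unadjusted p under 0.05 and 7 adjusted over the list alone, adjusted p = 0.000964 and adjusted p = 0.239 with an estimated correlation. Of 30 proliferation genes 2 fell, BUB1B (-1.74) and TTK (-1.08), 3 adjusted over the list alone, adjusted p = 0.0042 and adjusted p = 0.424 with an estimated correlation. Leaving out AsPC-1 PMA replicate 1, 4 metalloproteinases rose, 7 plasminogen system genes rose and 1 fell, 5 hypoxia and glycolysis genes rose and 1 fell, and 5 proliferation genes fell. Blocking on the passage, 3 hypoxia and glycolysis genes rose, 6 plasminogen system genes rose and 1 fell, and 6 proliferation genes fell. The other 13 lists did not pass, from sterol synthesis genes (adjusted p = 0.057) to mesenchymal genes (adjusted p = 0.908). With the passage as a block, sterol synthesis (adjusted p = 0.000275), actin cytoskeleton (adjusted p = 0.0391) and pancreatic duct genes (adjusted p = 0.0334) passed as well, and lost the call in that fit at adjusted p = 0.298, 0.347 and 0.422 with an estimated correlation. The same 3 lists passed without AsPC-1 PMA replicate 1 (adjusted p = 0.048 for each, and adjusted p = 0.532, 0.372 and 0.372 with an estimated correlation). In that fit 7 of the 15 lists that passed kept the call with an estimated correlation, epithelial junction genes (adjusted p = 0.00904 with an estimated correlation) among them.

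**Figure D1:**
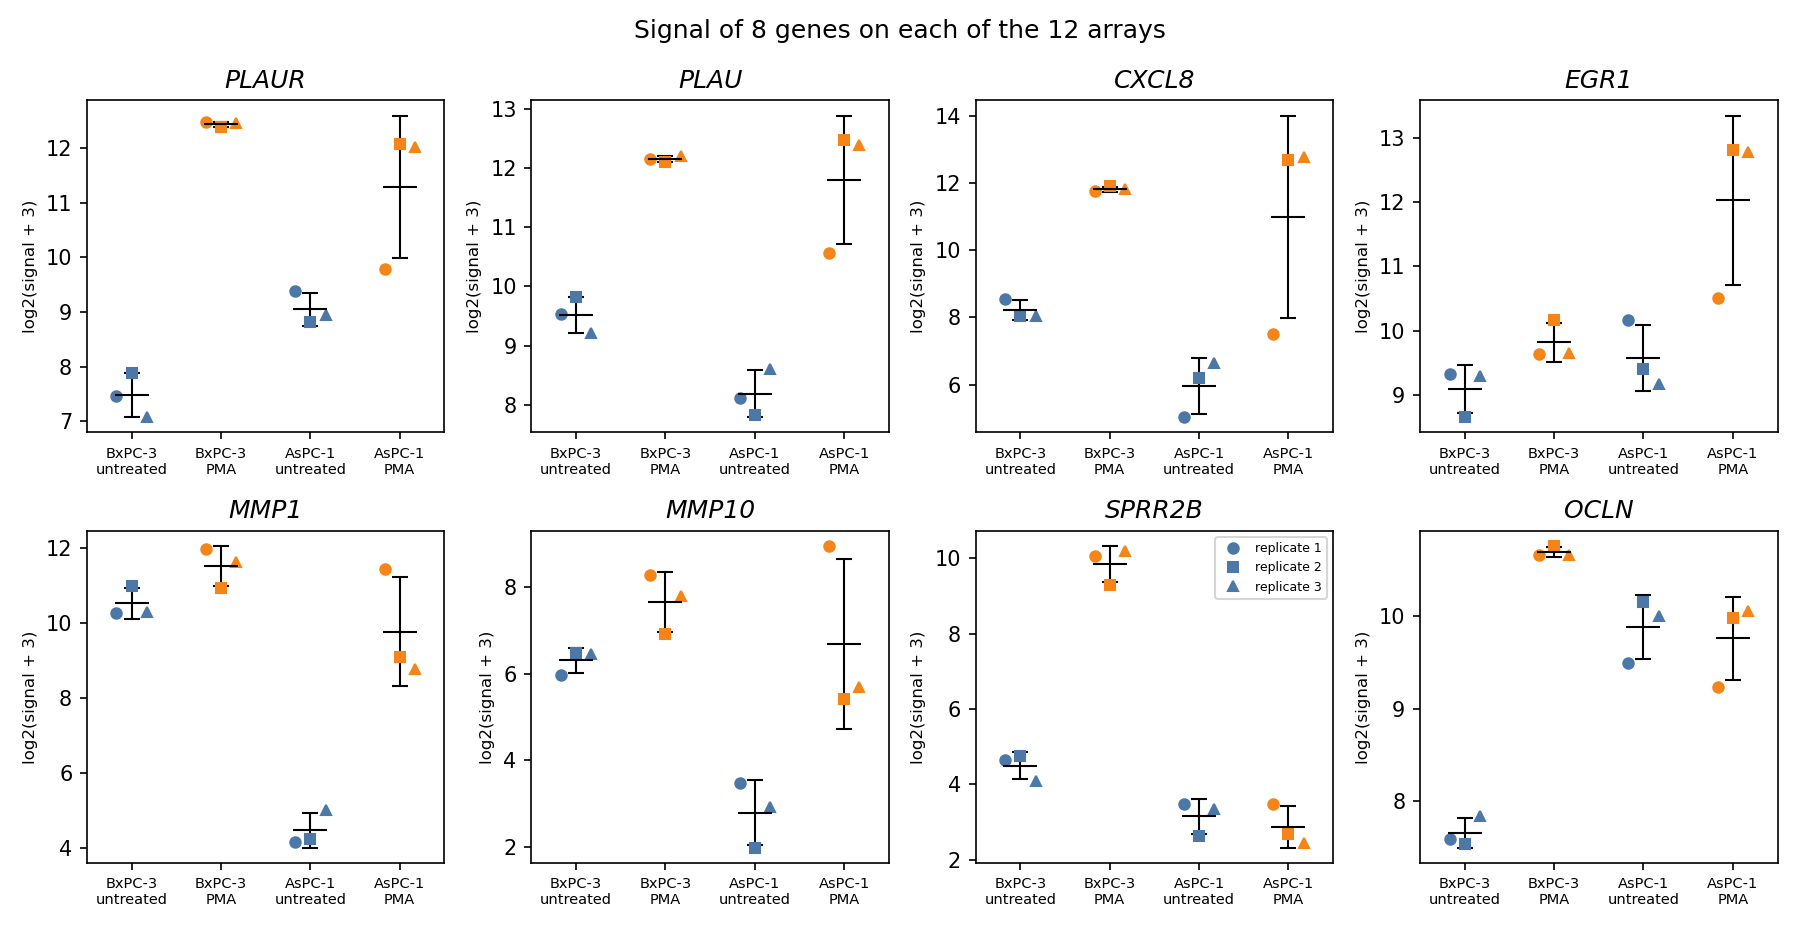
Log2(signal + 3) of 8 genes on each of the 12 arrays, by group, with symbols for replicate 1, 2 and 3 and bars for the mean and SD of 3 arrays. PLAUR reached a mean signal of 5540 in BxPC-3 after PMA, and AsPC-1 PMA replicate 1 lay at 180.5 for CXCL8, against 6610 and 6974 in the other PMA arrays, and at 2769 for MMP1, against 550.2 and 436.

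In all, 937 of 16099 genes passed in BxPC-3, 405 higher and 532 lower, a balance that turned to rising genes after median centring. Of the 937, 646 changed at least 2-fold. The groups did not overlap in 38.9% of genes, against 10% by chance. The count was 1645 with the passage as a block (922 of the 937 among them) and 2394 without AsPC-1 PMA replicate 1, which is no array of this comparison but enters the shared spread (all 937 among them). It was 408, 469 and 325 without untreated replicates 1, 2 and 3, and 428, 458 and 375 without PMA replicates 1, 2 and 3. Of the 45 named genes with a call, between 30 and 35 kept it in those 6 fits.

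In AsPC-1, PMA raised MMP1 from a signal of 20.2 ± 8.04 to 1250 ± 1320 (SD, n = 3), a log2 change of 5.29 ± 0.54 (SE, adjusted p = 0.000633). The neutrophil chemokines CXCL8 (5.03 ± 1.00), CXCL2 (4.28 ± 1.00) and CXCL3 (4.21 ± 0.96) and the cytokine IL1A (4.40 ± 0.62) rose, CXCL8 and CXCL2 on probe sets that related transcripts can share. PLAU rose by 3.62 ± 0.39 and PLAUR by 2.24 ± 0.46. PKDCC fell by 2.75 ± 0.62, as did the Notch-modifying enzyme LFNG (-2.39 ± 0.55) and FANCF (-2.29 ± 0.50). MMP9 (-0.06 ± 0.38, adjusted p = 0.955) and CDH1 (-0.14 ± 0.24, adjusted p = 0.838) did not pass. Without AsPC-1 PMA replicate 1 the log2 change was 4.46 for MMP1, 6.77 for CXCL8, 6.05 for CXCL2, 5.89 for CXCL3, 5.36 for IL1A, 4.24 for PLAU, 2.99 for PLAUR, -3.59 for PKDCC, -3.15 for LFNG and -3.10 for FANCF. CXCL8, CXCL2 and CXCL3 lost their calls without PMA replicate 2 (4.18, 3.49 and 3.48, adjusted p = 0.132, 0.22 and 0.203) and without PMA replicate 3 (4.14, 3.30 and 3.25, adjusted p = 0.131, 0.202 and 0.185). PKDCC lost its call without PMA replicate 2 (-2.07, adjusted p = 0.18) and FANCF without PMA replicate 3 (-1.66, adjusted p = 0.145), and IL1A kept its call there (3.77).

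The AsPC-1 PMA arrays differed among themselves. EGR1 had signals of 1458, 7160 and 7028 in PMA replicates 1, 2 and 3, against 1140, 674.2 and 570.2 untreated. DUSP1 had 1022, 6257 and 6562, against 226.1, 386 and 317.5. MMP1 went the other way, with 2769, 550.2 and 436, as did the metalloproteinase MMP10, with 489.1, 39.64 and 48.34. ITGA5, an integrin subunit, had 173.8, 157.2 and 160.9. The log2 change of MMP10 was 3.88, and 2.75 without PMA replicate 1 and 4.52 without PMA replicate 2.

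Of 26 immediate-early genes 9 rose in AsPC-1 (21 adjusted over the list alone), with EGR1 (2.46) and IER5 (2.15), adjusted p = 9.86e-21 and adjusted p = 0.0771 with an estimated correlation. Over all genes tested, 23 rose without PMA replicate 1. Of 22 ERK and PKC feedback genes 10 rose (11 adjusted over the list alone), with DUSP1 (3.51) and DUSP2 (2.67), adjusted p = 2.14e-12 and adjusted p = 0.0226 with an estimated correlation, a call lost with the passage as a block (adjusted p = 0.132 with an estimated correlation). Of 20 NF-kB target genes 3 rose (17 adjusted over the list alone), with TNFAIP3 (2.47) and SOD2 (2.03), adjusted p = 1.55e-15 and adjusted p = 0.0771 with an estimated correlation. Over all genes tested, 18 rose without PMA replicate 1. Cytokines had 7 of 26 rising (11 adjusted over the list alone), adjusted p = 2.92e-10 and adjusted p = 0.0771 with an estimated correlation. Of 30 proliferation genes 7 fell and 0 rose (19 and 1 adjusted over the list alone), with CCNA2 (-1.94) and TOP2A (-1.49), adjusted p = 2.46e-12 and adjusted p = 0.0771 with an estimated correlation. Over all genes tested, 18 fell and 1 rose without PMA replicate 1, when 11 cytokine genes rose, and 12 ERK and PKC feedback genes rose and 2 fell. With an estimated correlation, adjusted p was then 0.000254 for immediate-early and NF-kB target genes and 0.00372 for cytokines. In the fit with the passage as a block, 15 immediate-early and 9 NF-kB target genes rose, 11 ERK and PKC feedback genes rose and 1 fell, and 12 proliferation genes fell and 1 rose. Without PMA replicate 1 the log2 change was 3.22 for EGR1, 2.77 for IER5, 4.39 for DUSP1 and 3.31 for TNFAIP3.

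Genes of the cell surface and matrix followed in AsPC-1. Plasminogen system genes had 4 of 21 rising (6 adjusted over the list alone), with the protease inhibitor PI3 (3.5), adjusted p = 5.5e-07 and adjusted p = 0.0142 with an estimated correlation. Integrin, laminin and hyaluronan genes had 3 of 24 (7 adjusted over the list alone), with LAMB3 (2.72) and ITGA5 (2.67), adjusted p = 5.76e-08 and adjusted p = 0.0142 with an estimated correlation. With the passage as a block both lost that call (adjusted p = 0.132 each with an estimated correlation). Metalloproteinases had 2 of 29, MMP1 and MMP10 (2 adjusted over the list alone), adjusted p = 0.0445 and adjusted p = 0.106 with an estimated correlation. Actin and adhesion-complex genes had 3 of 27 (3 adjusted over the list alone), with RHOB (1.73) and PXN (1.37), adjusted p = 9.51e-06 and adjusted p = 0.0784 with an estimated correlation. Mesenchymal genes had 1 of 19, SNAI2 (1.48), with 2 adjusted over the list alone, adjusted p = 0.00882 and adjusted p = 0.153 with an estimated correlation. SRF and YAP target genes had 2 of 16 (4 adjusted over the list alone), with AMOTL2 (2.06), adjusted p = 0.011 and adjusted p = 0.248 with an estimated correlation. Without PMA replicate 1, 7 integrin, laminin and hyaluronan genes and 2 mesenchymal genes rose, 6 actin and adhesion-complex genes rose and 1 fell, and 3 SRF and YAP target genes rose and 3 fell. Blocking on the passage, 7 integrin, laminin and hyaluronan genes rose.

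Further kinds of genes passed as lists in AsPC-1. Growth factors had 2 of 19 rising (3 adjusted over the list alone), with HBEGF (2.64), adjusted p = 0.00496 and adjusted p = 0.0784 with an estimated correlation. Growth arrest and apoptosis genes had 2 of 20 (8 rose and 2 fell adjusted over the list alone), with CDKN1A (3.66) and MCL1 (1.89), adjusted p = 0.00371 and adjusted p = 0.0554 with an estimated correlation. Hypoxia and glycolysis genes had 1 of 20, DDIT4 (2.25), with 1 adjusted over the list alone, adjusted p = 0.000104 and adjusted p = 0.153 with an estimated correlation. Unfolded-protein and amino-acid stress genes had 2 of 22 (5 adjusted over the list alone), with PPP1R15A (2.67) and CEBPB (2.07), adjusted p = 5.25e-05 and adjusted p = 0.255 with an estimated correlation. Without PMA replicate 1, 6 growth factor genes rose and 1 fell, 7 growth arrest genes rose and 4 fell, and 7 hypoxia and 8 stress genes rose. With an estimated correlation, adjusted p was then 0.036 for growth factors and 0.0457 for stress genes. With the passage as a block, 4 growth factor genes rose and 1 fell, 5 growth arrest genes rose and 2 fell, and 4 stress genes rose. The other 10 lists did not pass, from NRF2 target genes (adjusted p = 0.151, and with the passage as a block 0.0461, or adjusted p = 0.561 with an estimated correlation) to protein kinase C and D genes (adjusted p = 0.998). Without PMA replicate 1, NRF2 target genes (adjusted p = 0.00974) and epithelial junction genes (adjusted p = 0.00914, against 0.216 with it) passed, and lost the call at adjusted p = 0.413 and 0.0653 with an estimated correlation. Of these, 3 NRF2 target genes rose, and 6 epithelial junction genes rose and 1 fell. In that fit 8 of the 17 lists that passed kept the call with an estimated correlation. The log2 change was then 3.41 for HBEGF, 4.38 for CDKN1A, 2.51 for MCL1, 3.08 for DDIT4 and 3.39 for PPP1R15A, and that of CDKN1A was 2.93 without untreated replicate 1.

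**Figure D2:**
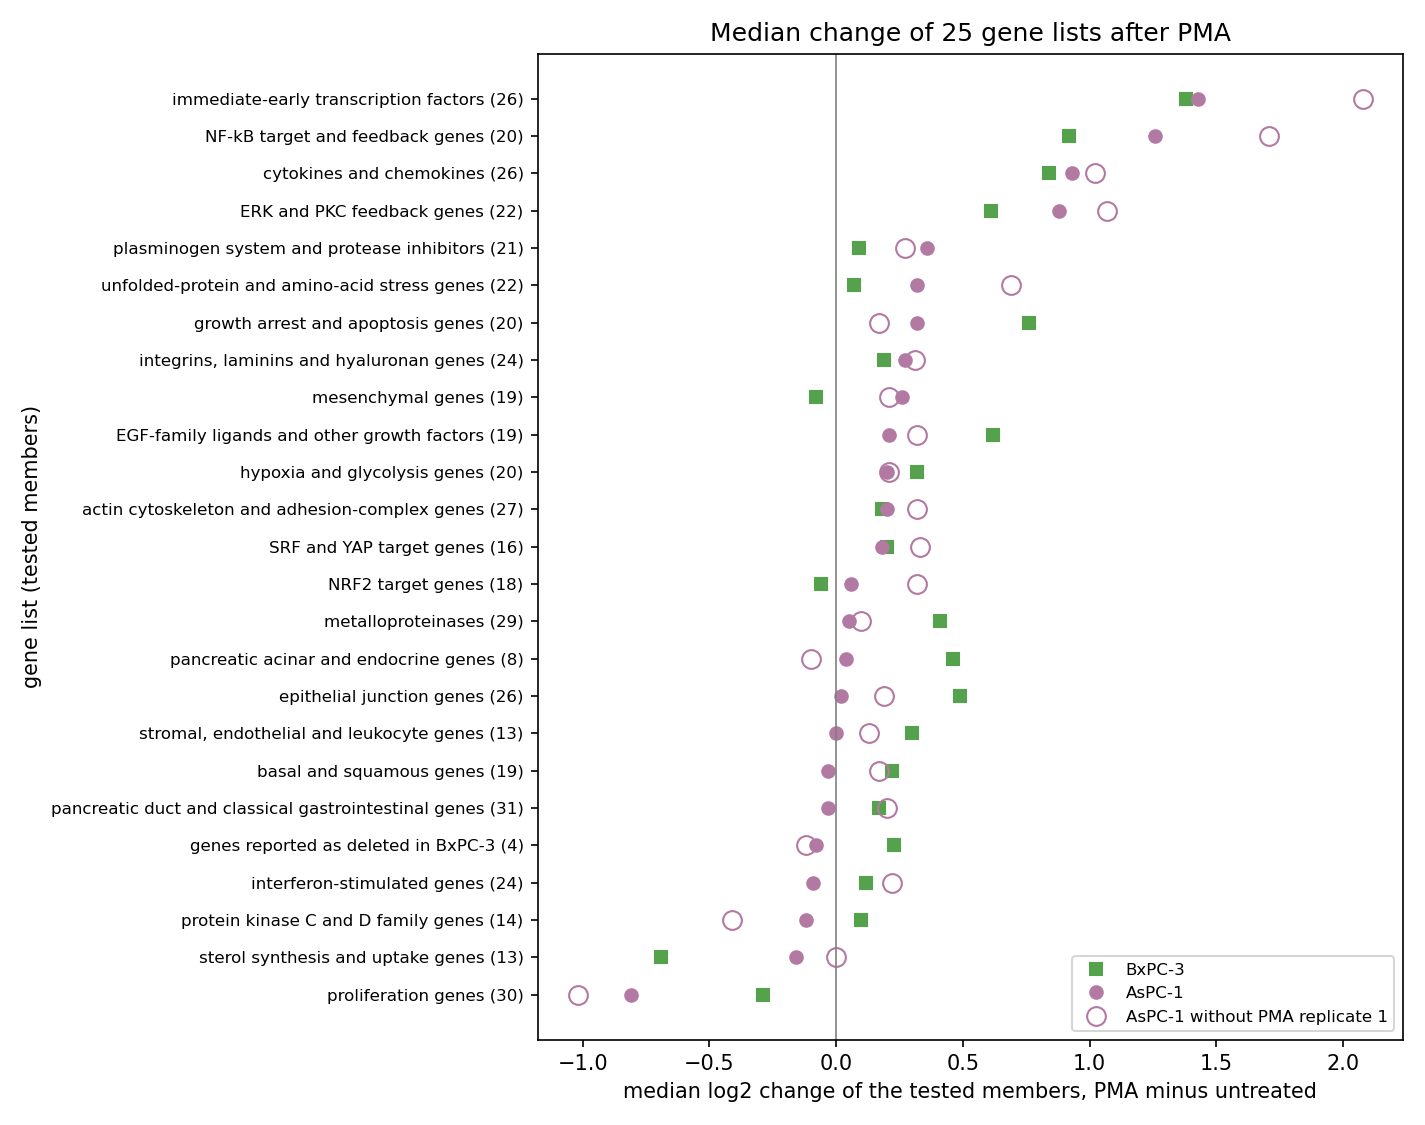
Median log2 change after PMA of the tested members of 25 gene lists (number of members in brackets) in BxPC-3 (squares), AsPC-1 (filled circles) and AsPC-1 without PMA replicate 1 (open circles). The median of immediate-early genes was 1.38 in BxPC-3 and 1.43 in AsPC-1, and that of proliferation genes was -0.29 and -0.81.

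In all, 316 genes passed in AsPC-1, 200 higher and 116 lower, and 251 of them changed at least 2-fold. The groups did not overlap in 14.4% of genes, against 10% by chance. The count was 904 with the passage as a block, 449 higher and 455 lower (314 of the 316 among them). It was 3147 without PMA replicate 1, 981 higher and 2166 lower (all 316 among them), so the balance turned to falling genes. It was 62 and 61 without PMA replicates 2 and 3, and 95 and 88 without untreated replicates 2 and 3. With the AsPC-1 arrays alone, limma called 0 genes, with 1526 at an unadjusted p under 0.05, and 40 of the 40 named genes with a call lost it. Without PMA replicates 2 or 3, 13 of the 40 kept it, and without untreated replicates 1, 2 and 3, 23, 17 and 16 did.

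Both lines shared 79 rising and 38 falling genes, where independent lists would share 5.03 and 3.83. The 2 calls of a gene rest on 1 estimate of its spread, which favours shared calls of either direction, so the expected counts here are low. Genes that rose in BxPC-3 and fell in AsPC-1 numbered 2, where 2.92 would be shared. For genes that fell in BxPC-3 and rose in AsPC-1 limma called 0, where 6.61 would be shared, and 28 at an unadjusted p under 0.05 in both, where 121 would be. PLAU, PLAUR, HBEGF, IL1A, CDKN1A, TNFAIP3, LAMB3 and PPP1R15A rose in both. The changes correlated at r = 0.413 across all genes, which are not independent replicates. The shared count of 117 was 386 with the passage as a block and 1253 without AsPC-1 PMA replicate 1, 372 rising and 881 falling, which turned the balance. It was 41, 46 and 37 without BxPC-3 untreated replicates 1, 2 and 3, 38, 61 and 38 without BxPC-3 PMA replicates 1, 2 and 3, 36 and 32 without AsPC-1 untreated replicates 2 and 3, and 27 and 26 without AsPC-1 PMA replicates 2 and 3.

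The difference of the responses was tested directly, as the signed log2 change in BxPC-3 minus that in AsPC-1. A smaller fall in BxPC-3 thus counts as a higher change. SPRR2B (5.63 ± 0.52, adjusted p = 0.000417), GRHL3 (4.86 ± 0.76, adjusted p = 0.0165), the tight junction gene OCLN (3.16 ± 0.32, adjusted p = 0.000574) and the membrane protease ST14 (2.57 ± 0.45, adjusted p = 0.0262) had the higher change in BxPC-3. MMP1 (-4.30 ± 0.77, adjusted p = 0.0304), the chemokine receptor ACKR3 (-4.47 ± 0.87, adjusted p = 0.0421), PI3 (-3.0 ± 0.51, adjusted p = 0.0228) and ITGA5 (-2.57 ± 0.45, adjusted p = 0.0278) had the lower change in BxPC-3. MMP1 started from 1520 ± 465 in untreated BxPC-3 and from 20.2 ± 8.04 in untreated AsPC-1. ACKR3 had signals of 324.9, 245.9 and 327.7 untreated and 51.82, 47.15 and 89.17 after PMA in BxPC-3. In AsPC-1 it had 20.88, 16.81 and 37.86 untreated and 30.76, 320.1 and 177.7 after PMA. PLAUR (2.72 ± 0.64, adjusted p = 0.115) and PLAU (-0.98 ± 0.55, adjusted p = 0.666) did not pass. Without AsPC-1 PMA replicate 1 both did, PLAUR at 1.97 (adjusted p = 0.00154) and PLAU at -1.61 (adjusted p = 0.00541). The difference was then -3.46 for MMP1 and -5.42 for ACKR3, and ACKR3 lost its call without AsPC-1 PMA replicate 2 (-3.79, adjusted p = 0.0811).

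Epithelial junction genes as a list had the higher change in BxPC-3, with 2 of 26 past the threshold (9 higher and 1 lower adjusted over the list alone), adjusted p = 0.000764 and adjusted p = 0.607 with an estimated correlation. Their median log2 difference was 0.52, and 0.15 without AsPC-1 PMA replicate 1 (adjusted p = 0.00942, and adjusted p = 0.114 with an estimated correlation). Proliferation genes had the higher signed change in BxPC-3 because they fell less there (median log2 change -0.29, against -0.81 in AsPC-1). Of 30 genes limma called 0 (0 adjusted over the list alone, 5 higher and 1 lower at an unadjusted p under 0.05), adjusted p = 0.000764 and adjusted p = 0.683 with an estimated correlation. Integrin, laminin and hyaluronan genes had the lower change, with 1 of 24 (3 adjusted over the list alone), adjusted p = 0.0271 and adjusted p = 0.607 with an estimated correlation. Their median was -0.21, and -0.13 without AsPC-1 PMA replicate 1 (adjusted p = 0.00987, and adjusted p = 0.295 with an estimated correlation). The other 22 lists did not pass (adjusted p = 0.073 or more). Leaving out AsPC-1 PMA replicate 1, 8 epithelial junction genes were higher and 1 lower, 6 proliferation genes were higher, and 1 integrin, laminin or hyaluronan gene was higher and 4 lower. Blocking on the passage, 4 epithelial junction genes and 1 proliferation gene were higher, and 1 integrin, laminin or hyaluronan gene was higher and 2 lower. In that fit sterol synthesis (adjusted p = 0.0014) and stress genes (adjusted p = 0.00763) passed with a lower change, and both lost the call at adjusted p = 0.622 with an estimated correlation. Without AsPC-1 PMA replicate 1, 12 lists passed, and immediate-early genes had the lower change (2 higher and 11 lower, adjusted p = 2.29e-10). Of the 12, 2 kept the call with an estimated correlation, immediate-early and NF-kB target genes (adjusted p = 0.00916 each with an estimated correlation).

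In all, 79 genes differed in response, 51 higher and 28 lower. The count was 126 with the passage as a block (68 of the 79 among them) and 713 without AsPC-1 PMA replicate 1 (all 79 among them). It was 32 and 43 without AsPC-1 PMA replicates 2 and 3, 14 and 43 without AsPC-1 untreated replicates 2 and 3, 15, 19 and 9 without BxPC-3 PMA replicates 1, 2 and 3, and 9, 23 and 31 without BxPC-3 untreated replicates 1, 2 and 3. Between 5 and 13 of the 19 named genes with a call kept it without any 1 array other than AsPC-1 PMA replicate 1. All 19 kept it without that array, which is no support for them, since the shared spread shrinks in that fit.

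Between the lines after PMA, BxPC-3 had the higher signal of PTGS2, the inducible cyclooxygenase (5700 ± 692 against 1.68 ± 2.31), and of the keratins KRT5 (3590 ± 289 against 7.53 ± 5.60) and KRT13 (log2 difference 9.24 ± 0.32, adjusted p = 1.96e-10). AsPC-1 had the higher signal of IGFBP3 (6500 ± 771 against 4.06 ± 2.80), the intestinal cadherin CDH17 (5730 ± 850 against 9.65 ± 2.16) and the mesenchymal filament VIM (7420 ± 429 against 91.4 ± 78.1). CDH1 was higher in BxPC-3 by 2.56 ± 0.24 and MMP1 by 1.75 ± 0.54 (adjusted p = 0.0232). PLAU (0.35 ± 0.39, adjusted p = 0.546), PLAUR (1.15 ± 0.46, adjusted p = 0.0698) and MMP9 (0.55 ± 0.38, adjusted p = 0.298) did not pass. MMP1 was higher by 2.58 without AsPC-1 PMA replicate 1, and the log2 difference of VIM (-6.92) was -7.66 and -5.83 without BxPC-3 PMA replicates 1 and 2. Signals of a few units lie near the floor, so these fold changes depend on the pseudocount.

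Of 19 basal and squamous genes 14 were higher in BxPC-3 after PMA and 0 lower (14 adjusted over the list alone), adjusted p = 3.4e-10 and adjusted p = 0.00555 with an estimated correlation. Of 30 proliferation genes 14 were higher (17 adjusted over the list alone), with CDC6 (2.03) and MCM5 (1.75), adjusted p = 0.000424 and adjusted p = 0.576 with an estimated correlation. Of 4 genes reported as deleted in BxPC-3, 3 were lower there (3 adjusted over the list alone), with CDKN2B (-7.08) and CDKN2A (-6.50), adjusted p = 0.00111 and adjusted p = 0.363 with an estimated correlation. CDKN2A was at -5.85 without BxPC-3 PMA replicate 3. The other 22 lists did not pass (adjusted p = 0.106 or more). Without AsPC-1 PMA replicate 1, immediate-early (adjusted p = 1.98e-07), ERK and PKC feedback (adjusted p = 0.047) and NF-kB target genes (adjusted p = 0.0205) passed as well, lower in BxPC-3. Immediate-early genes kept the call (adjusted p = 0.0221 with an estimated correlation), and the others lost it (adjusted p = 0.504 and 0.138 with an estimated correlation). The genes lower in BxPC-3 then numbered 17 in the immediate-early list, against 7 with that array, and 11 in the NF-kB target list, against 4. In all, 5390 genes differed, 2941 higher and 2449 lower in BxPC-3, and 2414 higher and 2843 lower after median centring. The groups did not overlap in 43.4% of genes, against 10% by chance.

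Untreated, the lines already differed in 5216 genes, 2699 higher and 2517 lower in BxPC-3, and 2508 higher and 2669 lower after median centring. The groups did not overlap in 50.6% of genes, against 10% by chance. The protease inhibitor CSTA (2940 ± 296 against 1.34 ± 0.479), the actin-binding CALD1 (2390 ± 287 against 0.654 ± 0.45) and MMP1 (6.04 ± 0.54, adjusted p = 1.4e-06) were higher in BxPC-3. VNN1 (2.34 ± 1.57 against 3360 ± 187), IGFBP3 (-9.54 ± 0.36), ZEB1 (-5.55 ± 0.29), the matrix gene LUM (52.3 ± 16.1 against 2480 ± 881) and PLAUR (-1.58 ± 0.46, adjusted p = 0.0167) were lower. SMAD4, a gene reported as deleted in BxPC-3, had a signal of 1.74 ± 2.48 there and 168 ± 17.9 in AsPC-1. Here too, signals of a few units, as of IGFBP3 and ZEB1 in BxPC-3, lie near the floor, so such fold changes depend on the pseudocount. Of 19 basal and squamous genes 16 were higher and 1 lower (16 and 1 adjusted over the list alone), adjusted p = 4.02e-11 and adjusted p = 0.00411 with an estimated correlation. The genes reported as deleted had 3 of 4 lower (4 adjusted over the list alone), adjusted p = 0.000676 and adjusted p = 0.288 with an estimated correlation. The other 23 lists did not pass (adjusted p = 0.135 or more, and for sterol synthesis genes with the replicate number as a block 0.0489, or adjusted p = 0.926 with an estimated correlation). Of the genes that differed untreated, 2095 were higher and 1781 lower in BxPC-3 after PMA as well.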

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

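All tests of AsPC-1 PMA replicate 1, and of the genes with the higher change in BxPC-3 except the one on shared probe sets, and the splits of both lines that part all passage pairs, were chosen after the result was seen.

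The PMA response of 79 genes differed between the lines by the test of the difference. The log2 difference, BxPC-3 change minus AsPC-1 change, was 5.63 for SPRR2B, 4.86 for GRHL3, 4.50 for MYRFL, 3.52 for IL36G, 3.5 for LURAP1L, 3.38 for NCF1, 3.16 for OCLN, 2.57 for ST14, 2.23 for SPRR1A, 1.77 for CXCL16, 1.41 for MMP7 and 1.32 for PMAIP1. It was -2.57 for ITGA5, -2.97 for MN1, -3.0 for PI3, -3.15 for ZNF18, -3.46 for VAV3, -4.30 for MMP1 and -4.47 for ACKR3. With 16 times the pseudocount the log2 difference was 3.87 for SPRR2B, 2.59 for GRHL3, 1.4 for MYRFL, 2.5 for IL36G and 1.76 for LURAP1L. It was then 0.63 for NCF1, 2.9 for OCLN, 2.15 for ST14 and 1.17 for SPRR1A. CXCL16, MMP7 and PMAIP1 were at 1.38, 1.16 and 1.22 in that setting. Without AsPC-1 PMA replicate 1 it was 4.11 for LURAP1L, -3.46 for MMP1 and -5.42 for ACKR3, and ACKR3 lost its call without AsPC-1 PMA replicate 2 (-3.79, adjusted p = 0.0811). As lists, epithelial junction genes (adjusted p = 0.000764), proliferation genes (adjusted p = 0.000764) and integrin, laminin and hyaluronan genes (adjusted p = 0.0271) differed, and all 3 lost the call with an estimated correlation (adjusted p = 0.607, 0.683 and 0.607 with an estimated correlation). In 6 of 100 drawn splits of the arrays within each line, the real one included, as many genes differed, with up to 2605. The other 5 all kept the real split of BxPC-3, so they hold its PMA response and do not test chance for this count. Of the 32 splits of both lines that part all passage pairs, 3 gave as many, the highest, 1860, being the real split with the labels of AsPC-1 turned, which adds the responses of both lines.

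Of the 51 genes with the higher change in BxPC-3, 51 stayed past the threshold without AsPC-1 PMA replicate 1 and 50 with 16 times the pseudocount, which decides nothing, since the spread shrinks in both fits and the calls grow from 79 to 713 and 161. By size, 51 kept over 50% of their log2 difference without that array, at over 2 standard errors from the spread of all 12 arrays. Their median was 2.23 with that array and 2.17 without. The test by size is no further support, since a gene called with all 12 arrays cannot lose that much when a single array is left out. For these 51 genes the difference thus does not rest on that array alone. In 28 of them it was smaller without the array, and whether the array adds to it stays open. The median of the epithelial junction list was 0.52 with that array and 0.15 without. With 16 times the pseudocount 43 kept over 50%, with a median of 1.40, which leaves noise of dim signals open. Of the 51, 33 rest on probe sets with no mark of shared transcripts, which argues against shared probe sets for these, and the other genes, SPRR2B, SPRR1A and NCF1 among them, stay open to it. A difference between the lines in the response of these genes may remain, as a hypothesis found on the same data.

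AsPC-1 PMA replicate 1 showed less of the response than PMA replicates 2 and 3. Over 1170 genes that passed and changed at least 2-fold in a fit of the BxPC-3 arrays alone, in which 3535 passed, the response taken against the untreated array of the same passage had a slope on the BxPC-3 change of 0.116 in passage 8, 0.554 in passage 10 and 0.65 in passage 12, which argues against a different starting level in passage 8 as the whole cause. An untreated culture under a treated label stays open. A first test counted 19 genes over 4-fold above all untreated AsPC-1 arrays, the one of the same passage included. It counted 48, 14 and 7 for untreated replicates 1, 2 and 3, each set only against the other 2, of other passages. That bar is lower, so the first test decides nothing. A second, written after the first was seen, counted 8 among genes that rose 4-fold elsewhere, against up to 2 for an untreated array. Taken alone, that would argue against an untreated culture. The 1157 genes that fell at least 2-fold without AsPC-1 PMA replicate 1 had a median log2 change of -1.37, and of 0.02 in that array. Dilution with untreated RNA may apply in part. In a first test the share of the response had an interquartile range over genes of 0.197, against up to 0.511 in BxPC-3 PMA arrays. The median share in AsPC-1 PMA replicate 1 was 0.0396, and the range of a share shrinks with the share, so that comparison decides nothing. In a second test, again written afterwards, 5 genes lay over 4-fold above the level of a common share, against up to 3. Of 981 genes that rose without AsPC-1 PMA replicate 1, 5 lay over 2-fold above both other PMA arrays in it, MMP1 (2769) and MMP10 (489.1) among them. Untreated RNA mixed with RNA like that of PMA replicates 2 and 3 cannot give such levels, so dilution alone does not account for these genes. A shorter, weaker or later response was not tested.

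Other splits of the 6 arrays were too few, at 10, for a share under 0.05. The real split gave 937 genes for PMA in BxPC-3, 5390 between lines after PMA and 5216 untreated, each with 0 in the highest of the other splits and 1 split as large. For PMA in AsPC-1, 3 of the 10 splits gave as many as the real 316. The highest, 1026, put PMA replicate 1 with untreated replicates 1 and 3, and kept passage 8 on one side. Among the 4 splits that part all 3 passage pairs, the highest other count was 0 in both lines. For the 117 shared genes, 2 of 100 drawn splits gave as many, the real one included, the highest other 162. In 88 of the 100 the real split of BxPC-3 was broken, and the highest shared count there was 0, so those splits could not test chance for that count. Of the 12 that kept it, 2 gave as many. Of the 32 splits that part all passage pairs in both lines, 8 kept it and the real one alone gave as many, the highest other 2. Neither 12 nor 8 splits are enough for a share under 0.05.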

How the results depend on the processing

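Pseudocounts of 16 times the one used and the fits without both AsPC-1 arrays of passage 8 were chosen after seeing the data, as were the fits of BxPC-3, of the untreated lines and of the lists without AsPC-1 PMA replicate 1, and an estimated correlation in that fit and under the replicate block. Causes were not tested unless stated. Of changes to the named genes and lists that left out no array, 2422 of 2600 gene results and 1390 of 1500 list results kept their direction and side of the threshold.

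All probe sets tested singly, which tests more features, gave 1681 for PMA in BxPC-3, 10079 untreated and 10600 after PMA between lines. The arrays of the comparison alone gave 3535 in BxPC-3, 0 in AsPC-1 and 0 shared. Without trend there were 113 in AsPC-1 and 35 shared, and with the mean of probe sets 179 and 75. Median centring gave 41 differing responses and 16 times the pseudocount 161. The replicate block gave 1645 in BxPC-3, 904 in AsPC-1, 126 differing responses, 386 shared and 5 lists for the difference, and moved no count between lines by over 1.5 times. Without both arrays of passage 8 there were 3769, 3442, 1187 and 1781, with 10 lists for the difference and 6 between lines after PMA. Leaving out 1 array gave 325 to 2394 in BxPC-3, 61 to 3147 in AsPC-1, 4300 to 6542 after PMA, 4124 to 6542 untreated, 9 to 713 differing and 26 to 1253 shared, with 12 lists for the difference and 6 after PMA without AsPC-1 PMA replicate 1. An estimated correlation left 1 list in BxPC-3, 3 in AsPC-1, 1 after PMA, 1 untreated and 0 for the difference (limma camera), with the replicate block 0, 0, 1, 1 and 0 in that order, and without AsPC-1 PMA replicate 1 7, 8, 2, 1 and 2, and fry called 9 in AsPC-1, 11 after PMA, 7 untreated and 0 for the difference. SREBF2 between lines after PMA turned to -0.15 with the mean of probe sets, and the plasminogen list there turned up with fry (−log10 p 1.80). Median centring moved the higher calls from 43.2% to 53.5% in BxPC-3 and from 63.3% to 75.9% in AsPC-1, and the median change of all genes from 0 to 0.131 and from -0.096 to 0.127. Between lines it moved the higher calls from 54.6% to 45.9% after PMA, with the median from 0.03 to -0.10, and from 51.7% to 48.4% untreated.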

Other observations

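The scan of gene families was chosen after the data were seen, and the further tests of the zinc finger genes were chosen after that family was noticed.

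Families of genes that share a symbol stem were scanned for calls after PMA, over 114 families of at least 15 tested members. In BxPC-3, 51 of 431 ZNF genes fell where 14.2 were expected and 1 rose (Fisher's exact test, adjusted p = 4.48e-13), and 8 of 41 ZBTB genes fell (adjusted p = 0.00561). In AsPC-1, 7 of 33 kinesin (KIF) genes fell where 0.238 were expected (adjusted p = 7.01e-07), and 5 ZNF genes fell (adjusted p = 1). DUSP phosphatase genes rose in both lines, 5 of 22 in each (adjusted p = 0.0138 in BxPC-3 and 0.000712 in AsPC-1). Without AsPC-1 PMA replicate 1, 93 ZNF genes fell in BxPC-3 (adjusted p = 5.69e-13) and 86 in AsPC-1 (adjusted p = 0.00405). Genes are not independent replicates in these tests, and the difference between lines was not tested for the family.

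For the ZNF genes in BxPC-3, 0 of 10000 sets of other genes matched on mean signal held as many falling genes, which argues against noise of dim probe sets as the whole cause. The odds ratio of 4.24 was 3.47 after quantile normalization and 3.99 after median centring, which argues against scaling. Among probe sets with no mark of shared transcripts it was 3.86 (Fisher's exact test, p = 4.1e-10), which argues against shared probe sets. The ACTB ratio of 3' to 5' signal was 2.56, 2.95 and 4.15 in the untreated BxPC-3 arrays and 1.84, 1.99 and 2.02 after PMA, while the GAPDH ratio overlapped, with 1.04, 1.06 and 1.12 untreated and 1.00, 1.07 and 1.02 after PMA. The bearing of these ratios on the ZNF genes was not tested. That ZNF genes fell as a family in BxPC-3 stays a hypothesis found and tested on the same arrays, and no biological explanation was tested.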
